A study of Mus musculus with 10 samples.

How the data were processed

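RNA-seq read counts per gene were available from 10 libraries of mouse cortex at E12.5, 5 from Emx2 knockout embryos and 5 wild type. Per the labels, total RNA was isolated with a column kit and libraries followed standard Illumina protocols. The deposited values are raw counts per Ensembl gene, not normalized, as whole numbers that sum to a different total in each library. Per the submitters' processing notes, the tools were bcl2fastq 2.20, STAR 2.7.8a and featureCounts 1.6.3-p1, and the builds named were GRCm39 and, unexpectedly for mouse samples, rn6. The notes used here give no parameters, strand setting, read length or annotation release. Reads of a gene and of an antisense or overlapping gene, such as Emx2 and Emx2os, therefore cannot be told apart, and how reads shared by near-identical copies were counted is not given in the sources used here.

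The files list 56748 gene identifiers, of which 52073 matched a symbol in the name table, and these held 98.4% to 99.4% of the counts per library. Biotypes and distances between genes came from the GENCODE annotation of GRCm38 by gene identifier. Because the submitters' notes name another build, no coordinates are printed. Total counts ran from 9720840 to 35674113 per library, and 25766 to 30115 genes had at least 1 read. The totals fell into 2 classes, 5 libraries of at most 14700549 counts (2 knockout, 3 wild type) and 5 of at least 24856930 (3 knockout, 2 wild type). Each of the 3 codes that end the sample titles holds both genotypes, but within every code the knockout libraries are of 1 size class and the wild-type libraries of the other. Within a size class the genotypes therefore share no code. The labels do not say what the code is. Libraries of different genotype deviated together from their group means where they shared the size class (mean residual correlation 0.13) and not where they did not (-0.12). Deviations from a group mean cancel within each genotype, so these 2 values are bound to each other and are not separate evidence.

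Libraries of a genotype were compared before averaging, and every pair differed by more than sampling noise (chi-square per gene of 8.29 to 21.3 over 20 pairs), so no pair was merged as a repeat deposit of 1 library. This does not show that libraries came from separate embryos. Genes were filtered with edgeR's filterByExpr (minimum count 10), which left 18163, and scaled by TMM. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with genotype as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values were computed from the deposited counts with TMM-scaled totals and are given as mean ± SD with n = 5 per genotype. Standard errors of log2 fold changes were derived from the F statistic.

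Before the data were examined, 32 gene lists (17 primary, 15 secondary) were fixed for tissues, cell types and pathways of the region, along with the tests and most alternatives. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation per list, and with fry, with Benjamini-Hochberg adjustment over the lists. Genes were named by a rule fixed at the same time: Emx2 and Emx2os, the 8 protein-coding genes with the largest positive and the 8 with the largest negative log2 fold change among those past the threshold with a mean of at least 1 CPM, up to 4 members of each primary and 2 of each secondary list past the threshold with the smallest p (1 member of a primary list where none passed), and the 5 genes of at least 100 CPM with the smallest p. The rule gave 99 genes, of which the text prints those that describe each group, and 1 is not reported here. A difference of the genotype effect between title codes was tested as an interaction in the 8 libraries whose codes hold 2 of each genotype. Changed genes within 10 Mb of Emx2 were compared with the rest by Fisher's exact test.

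The procedure was tested on simulated counts drawn from the means, dispersions and totals of these libraries for the knockout against wild-type comparison. Of 50 genes changed at each size, 32 were recovered at 1.5-fold, 41 at 2-fold, 43 at 4-fold and 48 at 8-fold. With 17810 genes tested, 3 of 17618 unchanged genes were called. These simulated counts changed far fewer genes than the 4039 called in the real comparison and held no shared difference between size classes. The rates of recovery and of false calls therefore do not carry over directly to the real comparison. Of 30 unchanged lists of independent genes camera called 0 (17768 genes tested). That simulation held no correlation between genes, so it says nothing of lists whose members vary together.

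Alternatives were other scalings and filters, DESeq2 1.42.0, limma-voom, the title code as a block or 1 code alone, Y-linked expression as a covariate, mitochondrial and blood genes left out, each library left out, stricter thresholds and other windows. After the data were seen, the size class was added as a block, alone and with the title code, each class was fitted alone, counts were thinned to the smallest total in all libraries and in the large ones alone, and choroid plexus, hem and cilia genes were left out. Random splits of the libraries numbered 100 of the 126 possible.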

Results

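Gene-level RNA-seq counts were compared between 5 libraries of cortex, the dorsal part of the embryonic telencephalon, from Emx2 knockout mouse embryos and 5 from wild-type embryos, all at stage E12.5. Emx2 is a homeobox transcription factor expressed in the dorsal telencephalon, and the comparison asks which transcripts differ there in embryos labelled as its knockout. The knockout libraries held 30902451, 27377755, 13794221, 24856930 and 14700549 counts and the wild-type libraries 11755375, 13565559, 35674113, 33236998 and 9720840 counts. The labels do not say that each library came from a separate embryo, so p-values measure the spread between these libraries, which may be partly technical. The first principal component of log2 CPM (31.6% of variance) separated the genotypes. The second (18.2%) separated the 5 large from the 5 small libraries, and each class held both genotypes.

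**Figure D1:**
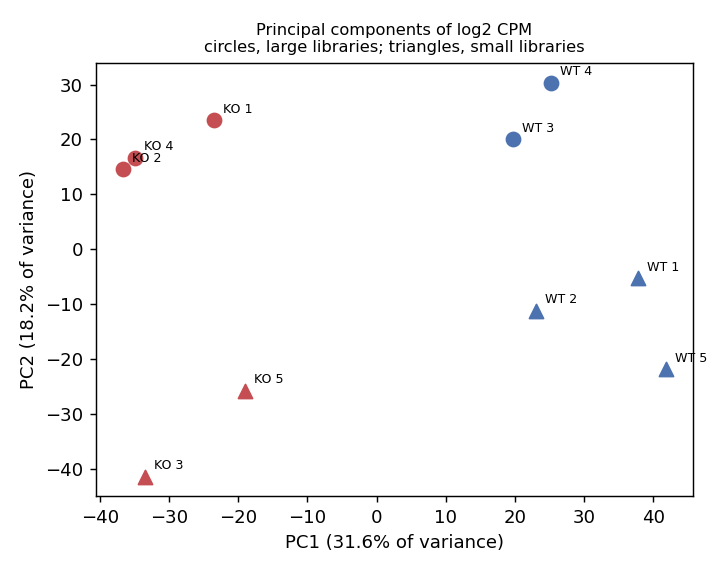
Principal components 1 and 2 of log2 CPM, with 1 point per library, colour for genotype (red, Emx2 knockout; blue, wild type) and shape for library size. The knockout libraries lie at negative values of component 1 and the wild-type libraries at positive values, while the large libraries lie at positive values of component 2 and the small ones at negative values.

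Transcripts assigned to Emx2 (ENSMUSG00000043969, on chromosome 19) were lower but far from absent in the knockout libraries. They stood at 123 ± 21.1 CPM against 186 ± 12.8 CPM in wild type (SD, n = 5 each), a log2 fold change of -0.59 ± 0.11 (SE, edgeR quasi-likelihood test, adjusted p = 0.00271). All 5 knockout libraries lay below the lowest wild-type library. The log2 fold change was -0.38 in the large and -0.91 in the small libraries, and with title code 241022 alone it did not pass (-0.49, edgeR adjusted p = 0.0653). Emx2os, an antisense transcript that overlaps Emx2, also fell (19.7 ± 1.82 against 34.1 ± 3.70 CPM, log2 fold change -0.80 ± 0.09, adjusted p = 6.05e-05). Counts over a whole gene do not show which part of it is deleted, and without a stated strand setting the reads of Emx2 and Emx2os cannot be told apart.

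**Figure D2:**
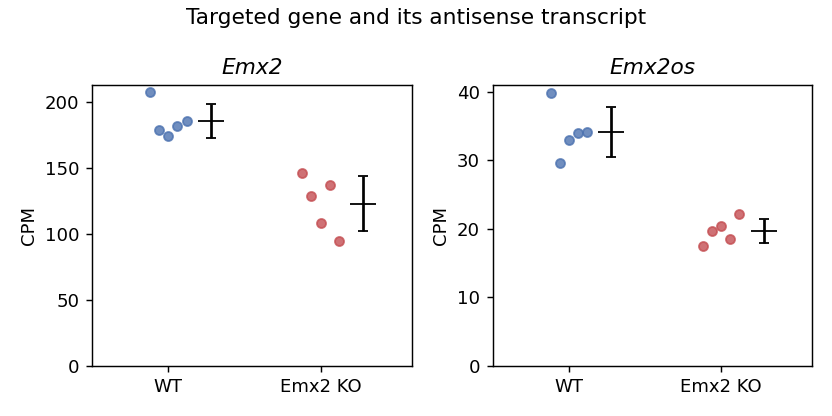
CPM (linear axis from 0) of Emx2 and Emx2os in each library, with bars at the mean ± SD of the 5 libraries per genotype. The 5 knockout libraries lie below the 5 wild-type libraries for both transcripts, with means of 123 against 186 CPM for Emx2.

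Of 18163 genes tested, 4039 differed between the genotypes, 2345 higher and 1694 lower in the knockout (edgeR, adjusted p under 0.05). Most differences were small, but large ones were more often decreases: 189 genes rose and 356 fell by at least 2-fold, and 26 rose and 87 fell by at least 4-fold. For 3030 of the 18163 genes tested the 2 groups of libraries did not overlap, which chance gives for 0.794% of genes. The balance of directions depended on scaling, with 1899 higher and 2245 lower under upper-quartile scaling and 1786 higher and 2464 lower with total counts alone. With size class as a block 3731 genes differed, and 3296 in the large libraries alone but 626 in the small ones alone. Fits of single title codes gave 530 genes (241022) and 1710 genes (14922). Within a size class the genotypes share no code, and within a code they share no size class. Such fits therefore cannot tell genotype from code or from size class.

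The deepest losses were in genes of the choroid plexus, the secretory epithelium that forms at the dorsal midline. Of 26 tested members of that list 19 fell, 0 rose and 7 did not pass (20 lower adjusted over the list alone), with a median log2 fold change of -1.61. Ttr, encoding the thyroid hormone carrier transthyretin, dropped from 116 ± 17.9 to 2.55 ± 1.41 CPM (log2 fold change -5.61 ± 0.29, edgeR adjusted p = 2.48e-06). Kcne2, a potassium channel subunit, went from 20.5 ± 3.28 to 0.393 ± 0.296 CPM (-5.78 ± 0.27), and the serotonin receptor gene Htr2c from 18.4 ± 0.646 to 0.748 ± 0.136 CPM (-4.66 ± 0.12). The list was lower by camera (adjusted p = 3.76e-44) and remained so with an estimated correlation (adjusted p = 8.63e-05). Its median was -1.55 in the large and -1.78 in the small libraries.

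Genes of the cortical hem, the WNT- and BMP-secreting margin between cortex and choroid plexus, were lower as well. Of 22 tested members 16 fell and 0 rose (19 lower adjusted over the list alone), with a median of -1.13. Wnt2b fell from 29.7 ± 2.28 to 5.97 ± 0.815 CPM (log2 fold change -2.31 ± 0.10, edgeR adjusted p = 8.60e-08) and Wnt5a from 58.8 ± 8.73 to 19.2 ± 3.29 CPM (-1.62 ± 0.13). Mcidas, a regulator of multiciliated cell differentiation, changed by -2.81 ± 0.31 and Trp73, a p53 family member found in hem-derived neurons, by -1.70 ± 0.18. Camera gave adjusted p = 8.84e-23 with the preset and adjusted p = 0.145 with an estimated correlation. The median was -0.80 in the large and -1.63 in the small libraries.

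**Figure D3:**
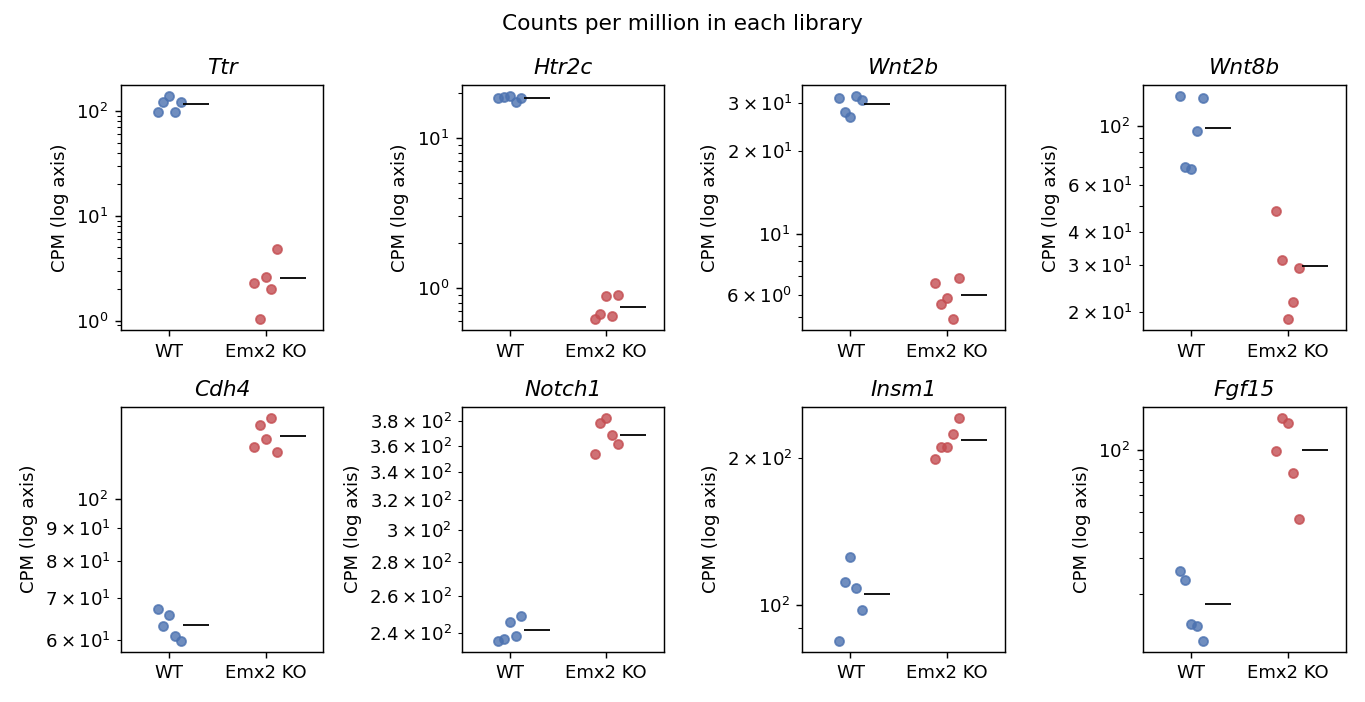
CPM (log axis) of 8 genes in each library, with a bar at the mean of the 5 libraries per genotype. Ttr, Htr2c, Wnt2b and Wnt8b lie lower in every knockout library than in any wild-type library, and Cdh4, Notch1, Insm1 and Fgf15 lie higher.

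The hippocampal primordium, which adjoins the hem, showed a mixed picture with a lower balance. Of 15 members 8 fell and 3 rose (10 and 3 adjusted over the list alone), with a median of -0.34. Wnt8b, also a member of the hem list, fell from 98.1 ± 29.4 to 29.9 ± 11.4 CPM (log2 fold change -1.69 ± 0.29, edgeR adjusted p = 0.00299). Fzd9 (-0.96 ± 0.10), Lmo2 (-1.05 ± 0.13) and Prox1 (-0.98 ± 0.15) fell too. The list was lower by camera with the preset (adjusted p = 0.000807) and with an estimated correlation (adjusted p = 0.046).

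WNT pathway lists were lower on balance while single members rose. These lists and the BMP list share members with the hem list, among them Wnt2b, Wnt5a, Axin2 and Bmp7. Their results are therefore not independent of it. Among 38 WNT ligands, receptors and antagonists 20 fell and 6 rose (23 and 7 adjusted over the list alone). Fzd7 fell (-1.16 ± 0.12) whereas Fzd8 rose from 180 ± 17.2 to 339 ± 20.1 CPM (log2 fold change 0.91 ± 0.07, edgeR adjusted p = 3.27e-06). Camera gave adjusted p = 3.21e-08, and adjusted p = 0.218 with an estimated correlation. Of 21 WNT/beta-catenin target genes 12 fell and 3 rose (13 and 3 adjusted over the list alone). Wif1, a secreted WNT inhibitor, fell from 6.76 ± 1.36 to 1.35 ± 0.962 CPM (-2.39 ± 0.39). This list gave camera adjusted p = 0.000566, adjusted p = 0.512 with an estimated correlation, and adjusted p = 0.422 in the large libraries alone. Of 26 BMP pathway and target genes 8 fell and 1 rose (8 and 3 adjusted over the list alone), among them Bmp5 (-1.97 ± 0.23), Bmp7 (-0.70 ± 0.14) and Id2, which rose (0.37 ± 0.07). Camera gave adjusted p = 0.008, adjusted p = 0.444 with an estimated correlation, and adjusted p = 0.239 in the large libraries alone.

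Genes of cortical progenitors were higher, by smaller amounts. Of 27 radial glia and apical progenitor genes, which mark the dividing cells that line the ventricle, 17 rose and 2 fell (19 and 3 adjusted over the list alone), with a median of 0.36. Notch1 rose from 241 ± 5.79 to 369 ± 11.8 CPM (log2 fold change 0.61 ± 0.03, edgeR adjusted p = 5.66e-07), as did the cadherin gene Cdh4 (0.99 ± 0.05) and the glutamate transporter gene Slc1a3 (0.67 ± 0.07), whereas Notch2 fell (-0.51 ± 0.04). The list was higher by camera (adjusted p = 1.50e-10) and with an estimated correlation (adjusted p = 0.046). Of 22 genes of intermediate progenitors, the neurogenic cells derived from radial glia, 13 rose and 1 fell (16 and 1 adjusted over the list alone). Insm1 rose from 106 ± 15.2 to 217 ± 16.1 CPM (1.04 ± 0.09) and Neurog1 from 27.9 ± 3.40 to 55.0 ± 5.22 CPM (0.98 ± 0.09). Here camera gave adjusted p = 4.18e-07, and adjusted p = 0.145 with an estimated correlation.

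Genes of FGF signalling and rostral patterning were mostly higher, 13 rising and 2 falling of 23 (15 and 2 adjusted over the list alone). Fgf15 rose from 17.9 ± 6.25 to 99.7 ± 40.1 CPM (log2 fold change 2.50 ± 0.35, edgeR adjusted p = 0.00101), and the FGF-responsive genes Etv5 (0.78 ± 0.09), Dusp4 (0.71 ± 0.06) and Spred2 (0.62 ± 0.05) rose too. The receptor gene Fgfr3 went the other way, from 447 ± 25.6 to 182 ± 23.5 CPM (-1.29 ± 0.08). Camera gave adjusted p = 1.51e-06, and adjusted p = 0.303 with an estimated correlation. Fgf8, named here after its value was seen, did not pass (0.28).

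Genes of the subpallium and the GABAergic lineage, normally expressed ventral to the cortex, were higher in the knockout but varied between libraries. Of 27 members 13 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 1.29. Pbx3 rose from 29.9 ± 9.20 to 89.2 ± 18.7 CPM (log2 fold change 1.57 ± 0.22, edgeR adjusted p = 0.000891) and Ebf1 by 0.86 ± 0.13. Foxp1, already at 71.3 ± 7.21 CPM in wild type, rose by 0.47 ± 0.07, which alone does not show ventral expression. Among genes named after their values were seen, Dlx2 (1.99), Gsx2 (1.86) and Gad1 (1.77) passed, while Gad2 (1.57), Isl1 (1.29) and Nkx2-1 (1.24) did not. Camera gave adjusted p = 3.05e-07, and adjusted p = 0.43 with an estimated correlation. The median was 1.63 in the large and 1.22 in the small libraries, where 0 members passed as higher and 1 as lower.

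Of 21 dorsal telencephalic patterning factors 8 rose and 2 fell (10 and 4 adjusted over the list alone), including the related homeobox gene Emx1 (109 ± 5.96 to 153 ± 15.7 CPM, log2 fold change 0.49 ± 0.07, edgeR adjusted p = 0.000303) and Sp8 (0.98 ± 0.17). Dmrta2, named because the series title mentions it, did not pass (0.15). Camera gave adjusted p = 0.0103, adjusted p = 0.572 with an estimated correlation, and adjusted p = 0.67 in the small libraries alone.

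**Figure D4:**
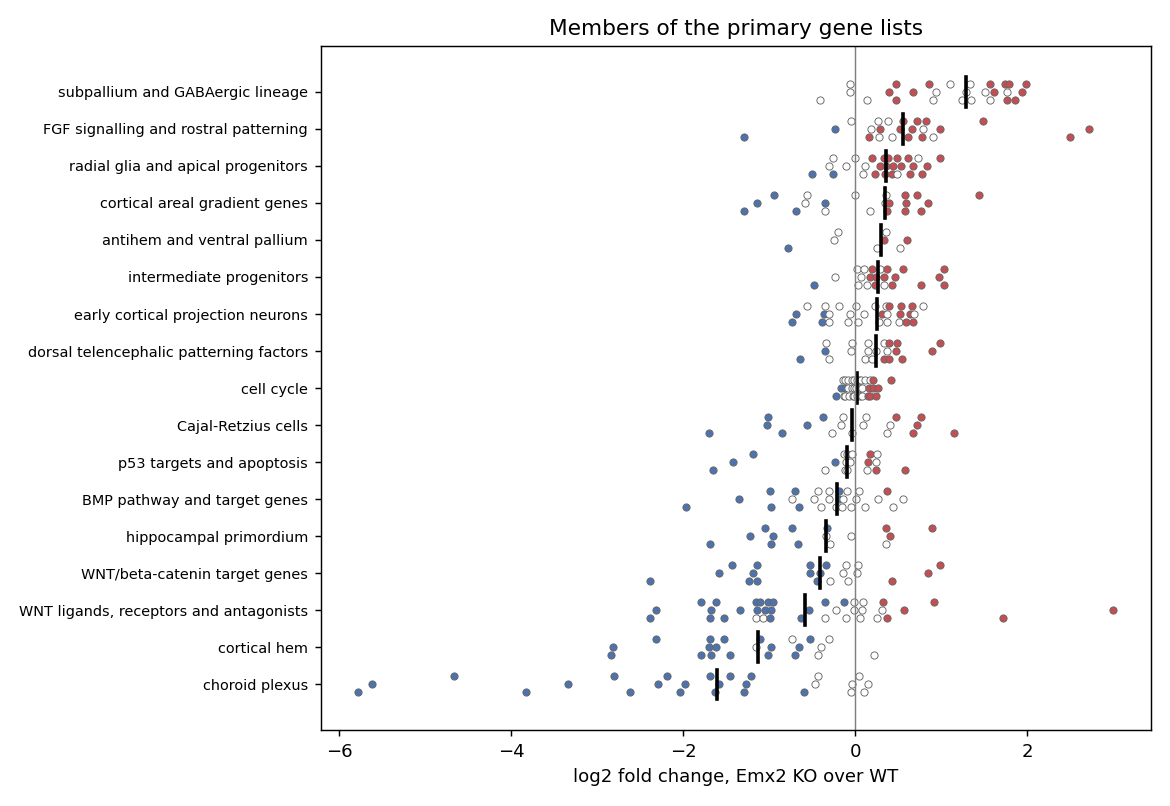
Log2 fold change (knockout over wild type) of each tested member of the 17 primary lists, with filled points for genes past an adjusted p of 0.05 (red higher, blue lower), open points for the rest, and a black line at each list's median. The medians run from -1.61 for choroid plexus and -1.13 for cortical hem to 1.29 for the subpallial list.

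Other primary lists did not pass camera, although members moved in both directions. Cajal-Retzius cell genes, which mark the earliest cortical neurons, had 5 higher and 6 lower of 19 (adjusted p = 0.456). Trp73, given above with the hem (-1.70 ± 0.18), and Cxcr4 (-1.02 ± 0.10) were lower. Ndnf (0.76 ± 0.15) and Tbr1 (0.67 ± 0.07), the latter also listed for projection neurons, were higher. Leaving out knockout replicate 1 gave the Cajal-Retzius list adjusted p = 0.0426, and the small libraries alone gave 0.00139. Early projection neuron genes had 8 higher and 4 lower of 30 (adjusted p = 0.126), with Tubb3 higher (0.64 ± 0.09) and Fezf2 lower (-0.69 ± 0.06). They passed without knockout replicate 1 (adjusted p = 0.0348) and without wild-type replicate 2 (0.0101). Areal gradient genes had 9 higher and 5 lower of 21 (adjusted p = 0.585), with Efna5 higher (1.44 ± 0.14) and Eya1 lower (-1.15 ± 0.11). Antihem genes had 2 higher and 1 lower of 8 (adjusted p = 0.46). Cell cycle genes had 8 higher and 3 lower of 36 (adjusted p = 0.464), and p53 targets 4 and 4 of 19 (adjusted p = 0.217), among them Cdkn1a, which fell by 1.19 on the log2 scale.

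None of the 15 secondary lists, which include markers of neighbouring or other tissue, passed camera in the comparison of all libraries. Adjusted p was 0.061 for meninges and 0.0649 for endothelium, both lower on balance, and these became 0.031 and 0.0233 with size class as a block. Both lists passed without knockout replicate 1 (0.0015 and 0.000846), knockout replicate 4 (0.0319 and 0.0251), wild-type replicate 3 (0.0492 each) and wild-type replicate 5 (0.0204 and 0.0162). Microglia (0.0116) and hypoxia (0.0348) passed without knockout replicate 1, and blood (0.034) without knockout replicate 3. For blood adjusted p was 0.359, and the blood list took 0.459% ± 0.195 of counts in knockout and 0.402% ± 0.130 in wild type. Mitochondrially encoded genes took 2.28% ± 0.091 of counts in knockout and 2.52% ± 0.092 in wild type, and the groups did not overlap (highest knockout library 2.35%, lowest wild-type library 2.39%, exact permutation test, two-sided, p = 0.00794, the smallest it can give). By Xist and Y-linked transcripts, 1 knockout and 3 wild-type libraries were of female type, and 4 and 2 of male type. For the other secondary lists adjusted p was 0.126 for microglia, 0.15 for surface epithelium, 0.186 for hypoxia, 0.196 for eye, 0.217 for mitochondrially encoded genes, 0.274 for neural crest, 0.456 for immediate early genes, 0.464 for histones, 0.691 for neighbours of Emx2, and 0.878 for the diencephalon, cholesterol synthesis and sex-linked genes.

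Camera with the preset correlation was a weak guide to the number of lists that differ. Of 100 splits of the 10 libraries, the real one included, 46 gave at least the 11 lists called here. The other splits kept 3 or 4 knockout libraries on 1 side, so part of that number can come from genotype. With an estimated correlation 3 lists were called, those of choroid plexus, hippocampal primordium and radial glia. Fry, which tests for movement in 1 direction on balance and does not compare a list with other genes, called 15 lists, the 11 of camera and those of antihem (adjusted p = 0.00949), eye (0.00722), p53 targets (0.0467) and neural crest (0.0467).

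Outside the lists, the largest decreases in protein-coding genes included the cilia genes Cfap65 (15.5 ± 1.69 to 0.788 ± 0.418 CPM, log2 fold change -4.39 ± 0.28, edgeR adjusted p = 2.06e-06) and Dnah6 (-4.08 ± 0.32), with Wdr63 (-4.58 ± 0.38), Map3k19 (-4.40 ± 0.30) and the transporter gene Slco1a4 (-4.13 ± 0.47). Apart from Fgf15, given above, and Prdm12, the largest increases were in genes of low abundance. They were led by the transcription factor gene Sox14 (0.102 ± 0.135 to 3.11 ± 2.16 CPM, 4.98 ± 0.74), Qrfpr (3.03 ± 0.45), the FGF list member Fgf3 (2.72 ± 0.61), Creg2 (2.71 ± 0.66), Gpr50 (2.66 ± 0.50) and Edar (2.64 ± 0.31). Prdm12 rose from 4.89 ± 1.76 to 25.6 ± 9.67 CPM (2.33 ± 0.32). In the small libraries alone Sox14, Fgf3, Creg2, Gpr50, Edar and Prdm12 did not pass, and in the large ones Qrfpr did not. The log2 fold change of Creg2 was 5.05 in the large and 1.74 in the small libraries and 3.41 without wild-type replicate 1, and that of Sox14 was 5.64 without wild-type replicate 4. Among abundant genes Fat3 fell from 216 ± 7.69 to 116 ± 9.44 CPM (-0.90 ± 0.05), while Pou3f2 (1.04 ± 0.07) and Myo10 (0.86 ± 0.05) rose.

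The genotype effect differed between the title codes 241022 and 14922 for 282 of 18430 genes (edgeR interaction, adjusted p under 0.05), of which 260 were not annotated as protein-coding and 0 were among the 99 genes chosen by the naming rule. In these 8 libraries the interaction is the same contrast as that between large and small libraries, so code and size class cannot be told apart within it. Changed genes were more frequent near Emx2, with 26 of 56 tested genes within 10 Mb against 22.4% elsewhere (odds ratio 3.00, Fisher's exact test, two-sided, p = 7.34e-05). The odds ratio was 3.64 within 5 Mb and 1.68 within 20 Mb, where 57 of 175 genes changed. Grk5 (0.70 ± 0.07) was among them. With title code 14922 alone the odds ratio was 1.86 (Fisher's exact test, p = 0.0782).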

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

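Tests of dissection, of the interaction against the remaining pair of libraries, of pseudogenes and of single lists over splits were chosen only after the results were seen. In 10 of 198 groups of 5 libraries (99 named genes, 2 genotypes), 1 library stood apart from the others by the ratio of its gap to the group's range, which is about the 1 in 20 that chance gives. Wild-type replicate 1 was the highest of its group for Sp8 (ratio 0.795, 84.6 CPM against 52.8 in the next), Foxp1 (0.837), Etv5 (0.72) and Bmp7 (0.715), and the lowest for Slc17a6 (0.783). Knockout replicate 1 was the highest for Trp73 (0.866, 25.8 CPM against 14.9) and Pdk1 (0.755). Knockout replicate 5 was the highest for Trpm3 (0.717) and the lowest for Pbx3 (0.843, 56.2 CPM against 94.5), and knockout replicate 4 was the lowest for Irx5 (0.883).

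Chance splits of the libraries can be excluded for the counts of changed genes. The real split gave 4039 changed, 2345 higher and 1694 lower genes, as large a count in 1 of 100 splits each, against at most 301 changed genes, or 153 in either direction, in any other. The split with 301 genes set the 5 large against the 5 small libraries, and with size class as a block the genotypes differed in 3731 genes. Chance cannot be excluded for the number of lists past camera's threshold, since 46 of 100 splits gave at least 11. The highest other gave 20. Yet every other split kept 3 or 4 of the 5 knockout libraries on 1 side, and the split with 20 lists kept 4. Such splits hold part of the genotype difference, so the 46 does not measure chance alone. By list, the real split gave the smallest unadjusted camera p (1 of 100) for choroid plexus (1.18e-45, nearest other 6.90e-13), cortical hem (5.53e-24 and 2.04e-23), hippocampal primordium (0.000227 and 0.000343), WNT ligands (4.01e-09 and 5.80e-09) and radial glia (1.41e-11 and 1.37e-08), by a narrow margin for hem, hippocampal primordium and WNT ligands. As small a p arose in 8 splits for intermediate progenitors, 11 for FGF signalling, 17 for WNT targets and 19 for the subpallial list. It arose in 20 for BMP and 24 for dorsal patterning factors. Chance cannot be excluded for these lists by this measure, though here too the splits hold part of the genotype difference.

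Lower choroid plexus and hem genes were found in both size classes. The median nearest to 0 of the 2 lists was -0.80 (quartiles -1.38 and -0.41), which argues against library size as the whole source. That median was of the hem list in the large libraries, where 6 members passed as lower. In the small ones its median was -1.63 and 12 passed. For choroid plexus 16 passed as lower in the large and 14 in the small libraries. Whether size class or title code adds to the hem difference cannot be told apart. Hem members outside the choroid plexus list had a median of -1.13 (quartiles -1.69 and -0.69). Whether they are also expressed in choroid plexus epithelium was not tested, and they include Mcidas, a regulator of multiciliated cells. Dissections that lost that epithelium but kept the hem are therefore not excluded by this value. A dissection that lost hem and plexus but kept the hippocampal primordium cannot be told apart from an effect of genotype, because hippocampal members outside the hem list went both ways (median -0.33, quartiles -0.90 and 0.25). A wider medial loss at dissection also stays open, as does loss or failed formation of this tissue in the knockout, which was not tested.

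The subpallial list had a positive median in both size classes, the lower being 1.22 in the small libraries (quartiles 0.59 and 1.51), which argues against library size as the source of the shift. In those 5 libraries 0 members passed as higher and 1 as lower. Ganglionic eminence tissue taken with the cortex in differing amounts stays open and may contribute: the 13 changed members varied together between libraries of a genotype, with a mean pairwise correlation of 0.51, just above the bound of 0.5 set for it. Random sets of as many changed genes had a median of -0.00204 and a 95th percentile of 0.10. The mean correlation was 0.65 among knockout and 0.38 among wild-type libraries. Ventral gene expression within the knockout cortex that varies between embryos would give the same correlation and was not tested.

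In the 282 genes whose genotype effect differed between title codes, the difference followed library size. Over these genes, the interaction had a rank correlation of 0.89 with the deviation of the remaining pair of libraries, which did not enter that fit and in which the knockout library is again the larger. Over all genes tested that correlation was 0.06. That value rests on the same pair of libraries alone, so it cannot show whether the genotype effect of other genes is free of library size. The correlations are across genes, which are not independent replicates. Depth of sequencing alone is argued against by thinning to equal totals, after which 172 genes still differed between the size classes. Reads shared with near-identical copies, handled differently in the 2 classes, is an explanation that stays open: 298 of the 318 genes that differed between the classes were pseudogenes (odds ratio 248, interval 156 to 419, Fisher's exact test). A difference in read length or layout between sequencing runs may underlie it, which the labels do not give, and a biological difference between codes was not tested further.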

How the results depend on the processing

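Fits of each size class, the size class as a block and thinning were chosen after the data were seen. Genotype coincides with title code in fits of 1 size class, and with size class in fits of 1 code. Changed, higher and lower genes numbered 530, 243 and 287 with title code 241022 alone, 1710, 1007 and 703 with 14922 alone, 626, 335 and 291 in the small libraries, 2181, 1349 and 832 at an adjusted p of 0.01, and 1212, 547 and 665 with a fold of at least 1.5. The large libraries, also 5, gave 3296 changed genes, and 2573, 1491 and 1082 when thinned to the smallest total, which argues against depth as the whole cause of the 626. All 10 libraries thinned gave 3429, with 79.7% of the 4039 kept. Other causes were not tested. With Y-linked expression as a covariate 3390 genes changed, 3209 of them shared with the 4039 (79.5%), and no list crossed the threshold. Leaving out 1 library gave 3072 to 3979 changed, 1783 to 2303 higher and 1289 to 1759 lower genes. In every setting, 0 of the genes shared with the 4039 changed sign. With the replicate block by title code 4023 genes differed, and no list crossed the threshold. The title codes share only a number in the labels. All 9 pairs of different genotype with the same code are of opposite size class. Their mean residual correlation was -0.099, against -0.119 over all pairs of different genotype and opposite size class, which include them. The pairs are few and share libraries, so whether a code adds to the deviation is not settled. The Emx2 log2 fold change was -0.49 with 241022 alone (adjusted p = 0.0653) and -0.66 to -0.51 with 1 library left out.

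Lists past the threshold numbered 18 in the small libraries, 3 with an estimated correlation, and 11 to 17 with 1 library left out. With an estimated correlation, adjusted p rose to 0.572 for dorsal patterning factors, 0.145 for cortical hem, 0.43 for the subpallial list, 0.303 for FGF signalling, 0.218 for WNT ligands, 0.512 for WNT targets, 0.444 for BMP and 0.145 for intermediate progenitors. In the small libraries it was 0.67 for dorsal patterning factors, 0.00139 for Cajal-Retzius cells and 0.000278 for projection neurons, and in the large ones 0.422 for WNT targets and 0.239 for BMP (thinned, 0.625 and 0.151). Projection neurons passed without a filter (0.0101) and with 14922 alone (0.00461). Leave-one-out ranges were 0.0426 to 0.916 for Cajal-Retzius cells, 0.0101 to 0.533 for projection neurons, 0.0015 to 0.244 for meninges and 0.000846 to 0.249 for endothelium. The diencephalic list turned to higher in the large libraries (0.00777, thinned 0.000595) and the blood list to lower in the small ones (0.00145). For these lists the cause was not tested.

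The interaction of title code and genotype gave 917 genes without a filter, 88 with at least 1 CPM in 5 libraries, and 167 to 239 with 1 library left out, the lowest without wild-type replicate 4. It gave 177, 186 and 179 without knockout replicates 1 and 3 and wild-type replicate 3. The cause was not tested. The odds ratio around Emx2 was 3.64 within 5 Mb, 1.68 within 20 Mb, 1.86 with 14922 alone (Fisher's exact test, p = 0.0782) and 2.39 to 3.71 with 1 library left out. Of the 98 named genes besides Emx2, 50 lost significance in the small libraries, 11 in the large ones, 44 with 241022 alone and 32 with 14922 alone, and 0 reversed in any setting. Depth may limit genes near 1 CPM most, which was not tested, and the smallest library held 9720840 counts.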

Other observations

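Gene families, taken as genes that share a symbol stem, were compared by a scan chosen after the data were seen. Of 243 families 17 passed camera with the preset correlation, and 1 of these, Cfap, also with an estimated correlation. The Cfap family, cilia- and flagella-associated proteins, had 16 of 23 members lower and 0 higher (median -1.02, adjusted p = 3.45e-15, and adjusted p = 0.031 with an estimated correlation), with medians of -1.01 in the large and -0.84 in the small libraries. The Dnah family of axonemal dynein heavy chains had 8 of 14 lower and 1 higher (median -0.74, adjusted p = 6.56e-07, and adjusted p = 0.149 with an estimated correlation). Leaving out choroid plexus, hem and cilia genes left 3913 changed genes.

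Transcription factor genes of the Pou and Sox families were higher on balance. Of 9 Pou genes 6 rose and 0 fell (median 0.87, camera adjusted p = 4.23e-10, and adjusted p = 0.0734 with an estimated correlation). Of 20 Sox genes 12 rose and 1 fell (median 0.38, adjusted p = 6.12e-06, and adjusted p = 0.127 with an estimated correlation). These directions, and those of the Cfap and Dnah families, held under each scaling.

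Mitochondrial transcripts with nuclear copies differed between library size classes. In the large libraries mt-Co2 stood at 0.792 ± 0.0787 CPM and mt-Co3 at 0.672 ± 0.232 CPM, against 8.82 ± 1.81 and 7.41 ± 1.15 CPM in the small ones (SD, n = 5 each). Levels of such genes and of pseudogenes are uncertain in these counts.

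The excess of changed genes around Emx2 was examined as a hypothesis, with the Fisher test planned, the test of other windows set before its value was seen, and the count over splits chosen after. The odds ratio was 3.00 (interval 1.70 to 5.26). Of 17700 windows within 10 Mb of other tested genes, 0% held as high a percent of changed genes as the 46.4% around Emx2. The highest held 40.6%. Tested genes around Emx2, 56 in number, lay only from -9.43 to 1.85 Mb of it. Other windows held at least 20 tested genes and were not matched for that number. A percent from few genes varies more. The windows therefore cannot decide whether clustering found along chromosomes in general explains the excess. Neighbouring windows overlap, so they stand for far fewer separate regions, and the Fisher test takes neighbouring genes as independent. The splits of the libraries say nothing here, since 82 of the 99 others called 0 genes. The members moved both ways. Strain DNA that flanks the targeted allele and effects of the allele on its neighbours both stay open and were not tested.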
